A study of Mus musculus with 4 samples.

How the data were processed

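MeRIP-seq was performed on hearts of C57BL/6 mice given a CHAPIR mimic (30 mg/kg) or a scrambled mimic (NC) for 14 days. The labels state the dose for the CHAPIR mimic and say that NC was given by the same procedure. Per the labels' protocols, mRNA was isolated from total RNA, fragmented chemically to 100 nucleotides, and enriched with an antibody against m6A. Libraries of enriched and input RNA were made with a stranded mRNA kit and sequenced for 150 cycles. Per the labels' protocols, adaptors were trimmed with cutadapt and reads were aligned with HISAT2. The submitters' processing notes name HISAT2 2.1.0 and the GRCm38 assembly. Peaks were called with exomePeak per the labels' protocols. Its version, its options, its threshold and whether it used the strand of the reads are not given in the sources used here. The deposited lists were called separately per condition, on 1 immunoprecipitated library over 1 input library, and no replicates were pooled. Read counts and alignments were not used here, so depth per sample is unknown and no precision from depth can be given.

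Each deposited list holds 1 line per peak and transcript, with chromosome, strand, exonic blocks, transcript, gene symbol and transcript region. The deposited fold enrichment is the authors' ratio of immunoprecipitated over input signal within a peak. The deposited p-value and FDR are the authors' values for that enrichment, and an FDR of 0 (126 NC peaks and 118 CHAPIR peaks) is a value too small to be written. The largest deposited FDR was 0.0501 in the NC list and 0.0468 in the CHAPIR list. The median fold was 3.49 (quartiles 2.51 and 5.23) in the NC list and 3.86 (2.74 and 6.03) in the CHAPIR list. These values were used only to describe, rank or filter peaks within a list. Medians of peak width were 238 exonic bases (150 to 391) in the NC list and 181 (121 to 300) in the CHAPIR list, with 55.4% and 68.5% of peaks in a single block. The peaks covered 3013 kb and 1751 kb of exons. The difference in width and number can change an overlap without any change in methylation, and therefore lists of equal length and short peaks were examined too.

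The coordinates were found to count from 0: 181 NC peaks and 386 CHAPIR peaks started 1 base before a RefSeq gene start, against 34 and 98 at it. Starts were raised by 1 base for printing. RefSeq gene names and spans for mouse held 5328 of the 5638 NC symbols and 4333 of the 4572 CHAPIR symbols, and 117 and 93 more by an older symbol.

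Overlap was computed with bedtools 2.31.1 on exonic blocks of the same strand, with at least 1 shared base. Shares were given with 95% Wilson intervals from scipy 1.17.1, which cover counting error only. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Genes were classed by the authors' symbol as present in both lists, NC only or CHAPIR only. The region of each peak was taken from the deposited annotation, over lines on protein-coding transcripts. Per the plan the region was to be read at the midpoint of a peak and near the stop codon. This, the DRACH motif of peaks, and matching of gene lists on exonic length need sequence and exon models of the assembly, which were not used here. The gene lists were therefore set against 10000 unmatched random lists of the same size, drawn with a fixed seed from the 6653 genes with a peak. The share of random lists that reach a count describes these lists and is no test of the conditions. Lists defined by a naming pattern (respiratory, ribosomal, mitochondrial and zinc finger genes) count only genes with a peak. The overlap and merging steps recovered 500 of 500 simulated pairs, and 3.80% of simulated lists without enrichment were reached by under 5% of random lists.

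Designs, gene lists and alternatives were fixed before the data were examined. Genes were named by a rule fixed with them: the 10 list only genes of smallest authors' FDR in each list and the 5 further ones of highest fold, without clone or model names, the 5 shared genes of smallest FDR in each list (ties by higher fold), a fixed set (Parp10, Mettl3, Mettl14, Wtap, Piwil4, Gsk3b, Nfatc4, Nppa, Nppb, Myh6 and Myh7), and per gene list up to 6 members in each list only class and up to 4 shared members. Values given for a gene are those of its peak with the smallest FDR, except where the highest fold is stated. Alternatives were other overlap rules, whole spans, strand ignored, an FDR at or under 1e-05, a fold of at least 4, lists of equal length, and protein-coding genes only. Some genes that the rule names are not reported here.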

Results

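N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, was mapped in hearts of C57BL/6 mice by MeRIP-seq. In this assay mRNA is cut into short fragments, the fragments that carry m6A are pulled down with an antibody, and they are sequenced beside the unselected input. The treated animals received a mimic of CHAPIR, a PIWI-interacting RNA (piRNA, a class of small RNA known best from germ cells), at 30 mg/kg from an implanted osmotic minipump for 14 days. The control animals (NC) received a scrambled mimic by the same procedure, and the labels put all samples at 2 weeks. Each condition had 1 immunoprecipitated library and 1 input library. Nothing therefore measured the spread between animals, no test between conditions was possible, and every difference below is a difference between these libraries. The measurements were 2 lists of peaks, 1 per condition, each called by the authors on the immunoprecipitated library over its own input. The NC list held 23155 peaks on 16428 transcripts of 5638 genes, and the CHAPIR list held 16562 peaks on 12173 transcripts of 4572 genes. The read depth behind the lists is unknown, so the limit of detection of either list could not be given.

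The first comparison asked which cardiac transcripts carried m6A peaks with added CHAPIR and which carried them with the scrambled mimic. Peaks were present in both lists for 3557 genes, in the NC list only for 2081 genes and in the CHAPIR list only for 1015 genes. Many shared genes had an authors' FDR of 0, the smallest value deposited. Taken in order of fold within each list, the leading ones were the nuclear long noncoding RNA Malat1, the mitochondrially encoded complex I subunits mt-Nd4, mt-Nd4l, mt-Nd5 and mt-Nd6, and Trdn, which encodes triadin of the calcium release complex. The leading Malat1 peak had the same position in both lists (chromosome 19, 5801943 to 5802640, GRCm38, minus strand, 656 exonic bases), with an authors' fold enrichment of 45.2 in the NC list and 112 in the CHAPIR list. Fold enrichments are the authors' values for immunoprecipitated over input signal. They are not scaled between the lists, and here they describe a peak within its own list only. In Trdn the leading peak was annotated to the coding sequence in the NC list (26.6-fold) and across the coding sequence and 3' UTR in the CHAPIR list (10.1-fold). These annotations belong to different transcripts of the gene. They therefore do not show a peak in another region of the same mRNA.

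Among genes with a peak in the NC list only, the smallest FDRs belonged to the X-inactivation transcript Xist and its antisense partner Tsix, and to the translation initiation factor gene Eif3b. The Xist and Tsix peaks overlap on opposite strands, and the authors' use of strand is not given in the sources used here, so their reads may not be separate. The leading Eif3b peak covered 655 exonic bases from the 5' UTR into the coding sequence (chromosome 5, 140419328 to 140425417) at 6.70-fold. The others chosen by FDR were the ribosomal protein genes Rpl19 (2.49-fold) and Rpl3l (2.30-fold), the X-linked histone demethylase gene Kdm5c (11.7-fold), the antigen peptide transporter gene Tap2 (17.2-fold), Gtf2f1 of the general transcription machinery (5.61-fold), Fam50a (10.3-fold) and Scaper (10.1-fold). The highest folds among the further NC only genes were those of the transcription factor gene Zbtb14 (47.7), the Wnt signalling gene Dvl1 (33.3), Wdr44 (32.7), Patz1 (30.0) and Auts2 (29.5).

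Among genes with a peak in the CHAPIR list only, Cox6a2, the muscle form of a cytochrome c oxidase subunit, had a peak across its coding sequence and 3' UTR (chromosome 7, 128205583 to 128205935) at 6.79-fold, and cardiac actin, Actc1, had a 3' UTR peak at 2.43-fold. The same group held the class I antigen presentation gene B2m (3.73-fold), the ferritin heavy chain gene Fth1 (14.9-fold), the mitochondrial transcripts mt-Nd1 (2.13-fold) and mt-Rnr1 (1.56-fold), the invariant chain gene Cd74 (4.32-fold), the sodium pump regulator gene Fxyd1 (5.67-fold), the ATP synthase gene Atp5g3 (8.54-fold) and the small heat shock protein gene Hspb7 (4.27-fold). The highest folds among the further CHAPIR only genes were those of the proto-oncogene Myc (57.2), Pttg1 (36.4), the mitochondrial ribosomal protein gene Mrpl39 (35.4), the carbonic anhydrase gene Car14 (35.4) and the ribosomal protein gene Rps25 (34.3). Other CHAPIR only genes also had equal folds, such as Ciart and Kdm5b (17.7) and Nfat5 and Zfp704 (14.6). Equal folds in unrelated genes can come from very few input reads. Without read counts, such high folds in either list cannot be told from well-measured ones. The order of the NC only and CHAPIR only counts depended on how the lists were cut. For lists of equal length only the NC list was cut, to its 16562 peaks of smallest p. Then 1112 genes were NC only and 1370 were CHAPIR only. The largest p kept was 2.57e-05 for NC and 0.00339 for CHAPIR, so the NC cutoff was stricter. At an FDR at or under 1e-05 in both lists, 1308 genes were NC only and 801 CHAPIR only. At a fold of at least 4 these counts were 1607 and 1417. A gene outside a list had no peak past the authors' threshold there, which leaves open whether its transcript was methylated or expressed.

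Peak positions were partly shared. A CHAPIR peak overlapped 11700 of the NC peaks (50.5%, 95% Wilson interval 49.9 to 51.2), and an NC peak overlapped 11970 of the CHAPIR peaks (72.3%, 71.6 to 73.0). Most of this gap went with the lengths of the lists, since the shares were 63.0% and 66.6% for lists of equal length. They were 32.9% and 47.4% when 50% of both peaks had to overlap. Of the 3557 genes in both lists, 3223 (90.6%) had overlapping peaks and 334 had peaks at separate positions. Peaks found in both lists were wider and had smaller FDRs than the rest, by the medians. In the NC list the median width was 330 exonic bases for overlapped peaks and 179 for the others, with 79.5% and 32.4% at an authors' FDR at or under 1e-05. In the CHAPIR list the widths were 238 and 146 bases, with 68.1% and 45.1% past that FDR. Median folds of overlapped and other peaks were 3.78 and 3.22 in the NC list but 3.86 and 3.87 in the CHAPIR list. A wider peak also meets a rule of 1 shared base more easily. The intervals cover counting error only, and lines of 1 gene repeat for its transcripts, so the peaks are not independent.

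The second comparison asked where along transcripts the peaks lay. Coding sequence held a larger share of the NC peaks and the 3' UTR a larger share of the CHAPIR peaks. On protein-coding transcripts, 50.1% of 17165 NC peaks (49.3 to 50.8) and 36.8% of 12612 CHAPIR peaks (36.01 to 37.69) lay wholly in the coding sequence (CDS). The 3' UTR held 23.1% of NC peaks (22.4 to 23.7) and 38.7% of CHAPIR peaks (37.9 to 39.6). Peaks that spanned the CDS and 3' UTR made up 18.2% (17.6 to 18.8) and 17.1% (16.4 to 17.7), and peaks wholly in the 5' UTR made up 2.27% (2.06 to 2.51) and 2.17% (1.93 to 2.44). Overlapped peaks share at least 1 base by definition, which limits how far their regions can differ, so a split by overlap does not locate the contrast. Among peaks that the other list did not overlap, the CDS held 61.7% of NC peaks and 16.0% of CHAPIR peaks, and the 3' UTR held 20.5% and 67.9%. Among overlapped peaks the CDS held 38.5% of NC peaks and 45.1% of CHAPIR peaks, the opposite order, and the 3' UTR held 25.6% and 27.1%.

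**Figure D1:**
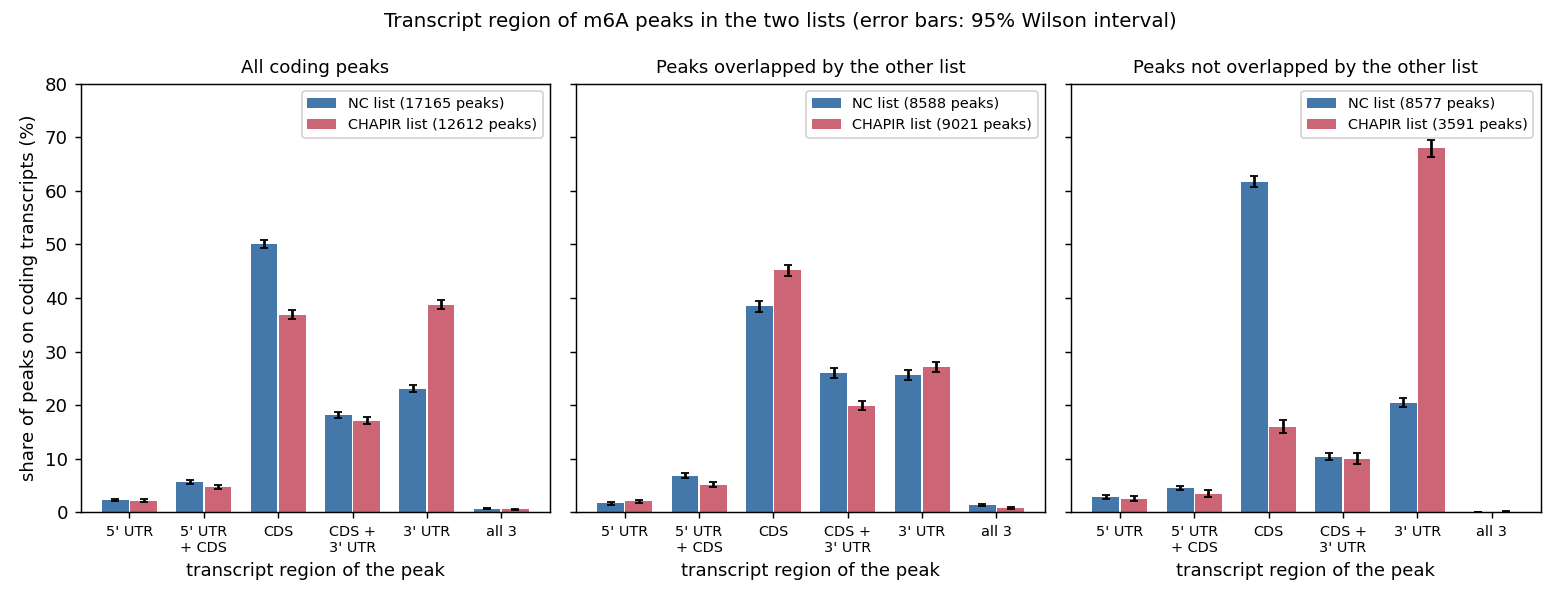
Share of peaks on protein-coding transcripts (%, vertical axis, with 95% Wilson intervals) by transcript region (horizontal axis) in the NC list (blue) and the CHAPIR list (red), for all peaks, peaks overlapped by the other list and peaks not overlapped by it. In the last panel the CDS bar is at 61.7% for NC and 16.0% for CHAPIR, and the 3' UTR bar is at 20.5% and 67.9%.

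The contrast was smaller within genes that had peaks in both lists, a setting chosen after the data were seen, where the CDS held 48.0% of NC and 40.8% of CHAPIR peaks and the 3' UTR held 22.5% and 33.9%. A peak wholly in the 3' UTR was present in both lists for 1240 of these genes, in the NC list only for 208 and in the CHAPIR list only for 607. A peak wholly in the CDS was present in both for 1107 genes, in the NC list only for 488 and in the CHAPIR list only for 231. A peak across the CDS and 3' UTR was present in both for 826 genes, in the NC list only for 495 and in the CHAPIR list only for 209, so peaks that reach into the 3' UTR from the CDS went the other way from peaks wholly in the 3' UTR. Of the CHAPIR only genes, 593 of 1015 (58.4%) had their best peak wholly in the 3' UTR and 83 (8.18%) had it wholly in the CDS. Of the NC only genes, 494 of 2081 (23.7%) and 776 (37.3%) did. Examples were the 3' UTR peaks of Actc1, B2m and Cd74 in the CHAPIR list and the CDS peaks of Fam50a, Gtf2f1 and Scaper in the NC list. Peaks were narrower in the CHAPIR list (median 181 exonic bases, against 238). Among single-block peaks of at most 200 bases, also chosen after the data were seen, the 3' UTR still held 60.9% of CHAPIR peaks and 43.5% of NC peaks.

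The third comparison grouped the genes by lists fixed before the data were examined, with markers of other cell types among them. Contractile genes mostly carried peaks in both conditions. Of 39 sarcomere and Z-disc genes with a peak, 35 were in both lists, among them Myh6, Myh7, Tnnt2, Tpm1 and Tcap. Over all genes with a peak, 3557 of 6653 were in both lists. Random lists of 39 genes had a median of 12 NC only members, and 0% held as few as 1. The CHAPIR only count of 3 was reached by 94.91% of them. Smyd1, a muscle methyltransferase gene, was NC only (1.90-fold, CDS), and Actc1, the chaperone gene Cryab (1.41-fold) and the Z-disc gene Myoz2 (2.16-fold) were CHAPIR only. Calcium handling genes and ion channel genes were also mostly shared (26 of 35), including Atp2a2, Casq2, Hrc and Trdn. The potassium channel genes Kcna5 (6.91-fold) and Kcnd2 (5.44-fold), the calcium channel gene Cacna1h (5.19-fold), Itpr1 and Stim1 were NC only, and Kcnd3, Kcnh2, Kcnip2 and Sln were CHAPIR only.

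In the list of fetal and stress genes of the heart, more members were CHAPIR only than NC only. Of 14 members with a peak, 7 were in both lists, 6 were CHAPIR only and 1, Nmrk2, was NC only (9.92-fold, 3' UTR). The CHAPIR only members were the natriuretic peptide gene Nppa (5' UTR, chromosome 4, 148000722 to 148000811, 7.59-fold, FDR 1.26e-66), the atrial light chain genes Myl4 (3.18-fold) and Myl7 (1.51-fold), the atrial calcium pump regulator gene Sln (4.75-fold), Hopx (9.36-fold) and Acta2 (3.28-fold). The shared members included Myh6, Myh7, Ankrd1 and Atp2a2, and Nppb had a peak in neither list. Several of the CHAPIR only members are atrial genes, and the amount of atrial tissue in each sample is unknown. The count is therefore no measure of a stress response. As a description of these lists, 1.29% of 10000 random lists of 14 genes held as many CHAPIR only members. With lists of equal length that share was 9.43%.

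Among genes of energy metabolism, the skew was clear for nuclear-encoded oxidative phosphorylation genes. Of 65 with a peak, 29 were CHAPIR only (44.6%, 33.2 to 56.7), 35 were in both lists and 1, Atp5l, was NC only. None of 10000 random lists of that size reached 29, and their median was 10. The CHAPIR only members included Cox6a2, Cox7a1 (3.16-fold), Cox5b (5.09-fold), Atp5j (4.26-fold) and Sdhb of complex II (2.99-fold). In 25 of the 29 the best peak touched the 3' UTR, and in 25 it had an FDR at or under 1e-05. Fatty acid and glucose genes had 26 shared, 10 CHAPIR only and 3 NC only members. The CHAPIR only members included the fatty acid oxidation genes Acadm (6.63-fold) and Hadhb (2.61-fold), the fatty acid transporter gene Cd36 (6.43-fold) and the insulin-responsive glucose transporter gene Slc2a4 (5.07-fold). The NC only members were Cpt1a (4.27-fold), Ldha and Lipe, and 6.50% of random lists reached the CHAPIR only count. Mitochondrially encoded genes had 15 shared, 3 NC only and 3 CHAPIR only members. Random lists had a median of 7 NC only members, and 97.99% of them reached 3. The CHAPIR only count was reached by 63.95%.

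Cytosolic ribosomal protein genes resembled the respiratory genes. Of 62 with a peak, 23 were CHAPIR only (37.1%, 26.2 to 49.5), 34 were in both lists and 5 were NC only. The CHAPIR only members included Rpl41 (2.70-fold), Rplp0 (10.7-fold), Rpl22 (3.22-fold) and Rps15 (2.34-fold), and the NC only members were Rpl19, Rpl3l, Rpl3, Rpl7 and Rpl10a. No random list reached 23, and 0.34% of lists matched on genomic span, added after the data were seen, did. Several ribosomal protein genes have processed copies elsewhere in the genome, so reads assigned to them are uncertain.

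Zinc finger genes lay on the other side. Of 124 zinc finger genes of the Zfp series, 65 were NC only (52.4%, 43.7 to 61.0), 52 were in both lists and 7 were CHAPIR only, and no random list reached 65. The NC only members included Zfp768, Zfp219, Zfp787, Zfp609 and Zfp710, with folds from 3.97 to 6.73 at their best peak, and the shared ones included Zfp106, Zfp91, Zfp970 and Zfp622. Zfp36, an mRNA decay factor of the same naming series, was CHAPIR only (7.28-fold). The excess depended on list length: with lists of equal length 25 of 84 were NC only (29.8%) and 14 were CHAPIR only, and 1.47% of random lists reached the NC only count. With peaks at an FDR at or under 1e-05 it stayed, with 29 of 55 NC only (52.7%), reached by 0.01% of random lists. Only 13 of the 65 had a best FDR that small, so the rest of the 29 had a CHAPIR peak of larger FDR. Of 48 chromatin regulators, 32 were in both lists, 14 were NC only, among them Kdm5c, Kdm3b (8.69-fold), Dnmt1 (6.67-fold), Ehmt1 (5.36-fold) and Tet3 (13.2-fold), and 2, Kdm5b and Tet2, were CHAPIR only. That NC only count was reached by 67.6% of random lists. With peaks at an FDR at or under 1e-05, 19 of 41 were NC only (46.3%), a count reached by 1.8% of random lists, but 10 of the 14 had a best FDR that small, so the rest of the 19 had a CHAPIR peak of larger FDR. With lists of equal length 11 of 45 were NC only, reached by 26% of random lists.

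Of the fixed lists of cell type markers, macrophage markers and adipocyte, epicardial and glial markers lay apart from most random lists. Endothelial, fibroblast and smooth muscle markers did not: their NC only counts were reached by 83.56%, 85.06% and 55.05% of random lists, and their CHAPIR only counts by 96.97%, 45.48% and 86.64%. Of 14 macrophage and immune cell markers with a peak, 9 were CHAPIR only, including Cd74, the class II gene H2-Aa (4.41-fold), the complement genes C1qb (4.42-fold) and C1qc (6.29-fold), Lyz2 (3.23-fold) and Laptm5 (5.38-fold). C1qa, Mrc1, Cd163 and Tlr4 were in both lists and F13a1 was NC only. No random list reached 9 CHAPIR only members, and 0.15% did with lists of equal length. All 5 adipocyte, epicardial and glial markers with a peak were NC only, among them the adipocyte genes Adipoq (3.22-fold), Plin1 (17.2-fold), Cfd (1.88-fold) and Cidea (2.75-fold). That count was reached by 0.26% of random lists, and the 3 of 3 at an FDR at or under 1e-05 by 2.68%. Xist and Tsix peaks were NC only, and peaks on the Y-linked genes Ddx3y and Eif2s3y were CHAPIR only, both named after their values were seen. The sex of the animals is not given in the labels. The comparison covered 21 gene lists and 42 counts.

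**Figure D2:**
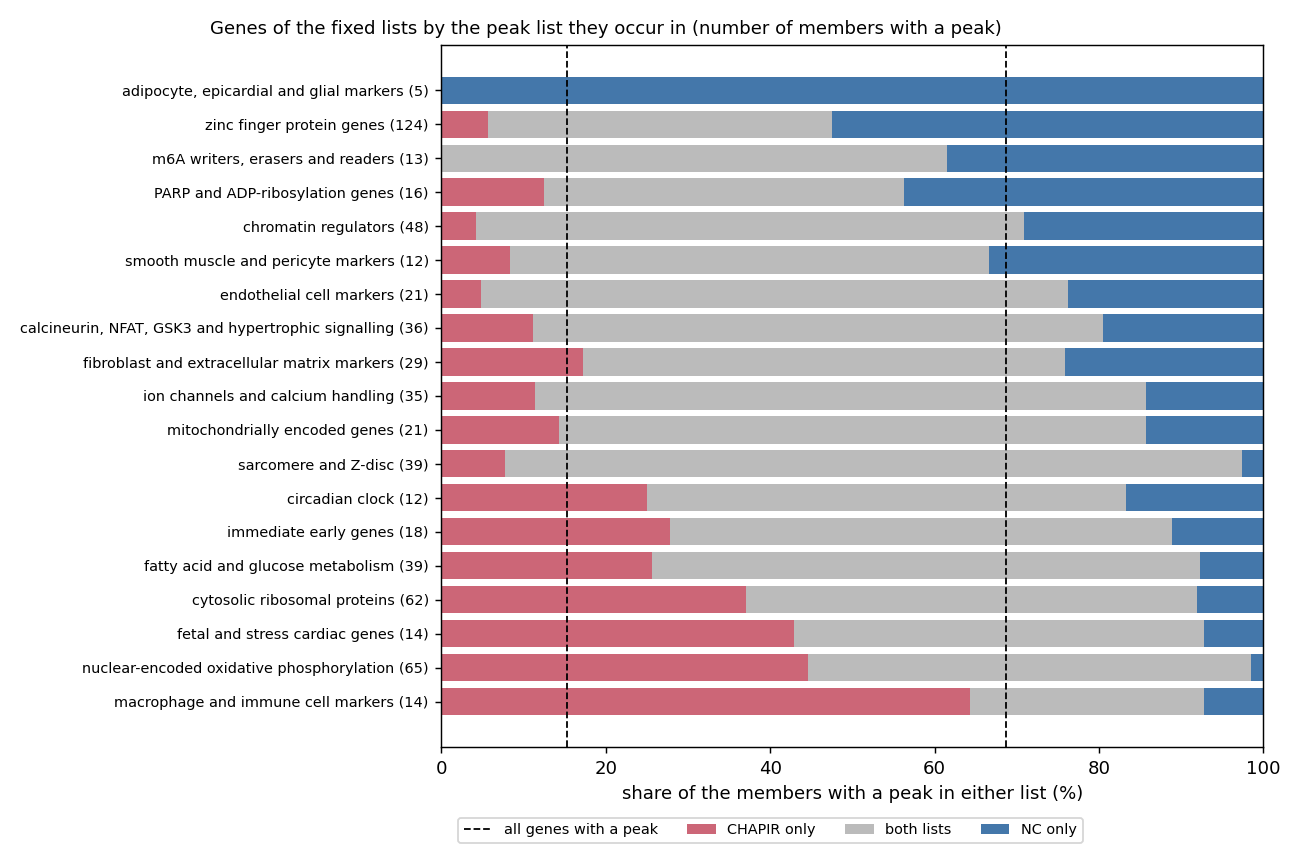
Share of the members with a peak in either list (%, horizontal axis) that were CHAPIR only (red), in both lists (grey) or NC only (blue), for each fixed gene list with at least 5 such members (vertical axis, number of members with a peak in brackets). Dashed lines mark the shares over all genes with a peak, 15.3% CHAPIR only and 31.3% NC only. Macrophage markers and oxidative phosphorylation genes lie furthest to the CHAPIR side, and adipocyte, epicardial and glial markers and zinc finger genes furthest to the NC side.

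The fourth comparison concerned the m6A machinery, hypertrophic signalling and Parp10. From knowledge outside these data, the study followed m6A on the mRNA of the ADP-ribosyltransferase PARP10 under CHAPIR. Of 13 genes of m6A writers, erasers and readers with a peak, 8 were in both lists, among them Wtap and Zc3h13 of the writer complex, the reader gene Ythdc1, and Hnrnpa2b1 and Hnrnpc. The other 5 were NC only: the writer complex genes Virma (4.52-fold), Rbm15b (3.91-fold) and Rbm15 (3.10-fold), the reader gene Ythdf1 (2.65-fold) and the eraser gene Fto (2.21-fold). None was CHAPIR only, and 38.02% of random lists reached the NC only count. Mettl3 and Mettl14, the catalytic core, had a peak in neither list. Of the piRNA pathway genes only the helicase gene Mov10l1 had peaks, in both lists and in its 3' UTR, and Piwil4 had none.

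In hypertrophic signalling, 25 of 36 genes with a peak were in both lists, 7 were NC only and 4 were CHAPIR only. The shared genes were led, by FDR in the NC list, by Camk2g, Pik3ca, Rock2 and the calcineurin regulator gene Rcan2. Gsk3b, a kinase that opposes NFAT activity, had a 3' UTR peak in the NC list only (chromosome 16, 38242997 to 38243177, 6.35-fold, FDR 7.76e-07). The calcineurin subunit gene Ppp3cb (3.09-fold), the histone deacetylase genes Hdac4 and Hdac5, Igf1r and Myocd were also NC only. Mtor (4.68-fold), Akt2 (2.20-fold), Camk2a (3.66-fold) and Nfat5 (14.6-fold) were CHAPIR only, and Nfatc4 was in neither list. Random lists reached the NC only count in 96.2% of draws and the CHAPIR only count in 82.2%.

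Parp10 had peaks in both lists at the same 2 places of the gene (chromosome 15, 76232995 to 76243440, minus strand). Near the 3' end, annotated as 3' UTR on both protein-coding transcripts, the CHAPIR peaks covered 240 bases from 76232975 to 76233214 on 4 transcripts, with folds from 4.58 to 5.85. The NC peaks covered 212 bases from 76233003 to 76233214, with folds from 3.49 to 3.54. On both protein-coding transcripts the peak had the same position in the 2 lists, 210 bases from 76233003 to 76233212. There it had 4.58-fold and FDR 2.29e-06 in the CHAPIR list, and 3.49-fold and FDR 0.000617 in the NC list. The 240-base peak with 5.85-fold and FDR 2.24e-09 lay on a transcript annotated for nonsense-mediated decay. In the coding region the CHAPIR peaks covered 155 bases from 76240774 to 76240928 on 3 transcripts, with folds from 2.76 to 2.81. The NC peaks there covered 566 exonic bases from 76240417 to 76241180, with folds from 5.33 to 5.63. Within the CHAPIR list the peak near the 3' end had the higher fold and the smaller FDR (2.24e-09 at best), and within the NC list the coding peak did (5.01e-13 at best). The folds of the lists are not scaled to each other, so no change in Parp10 methylation could be computed from them.

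**Figure D3:**
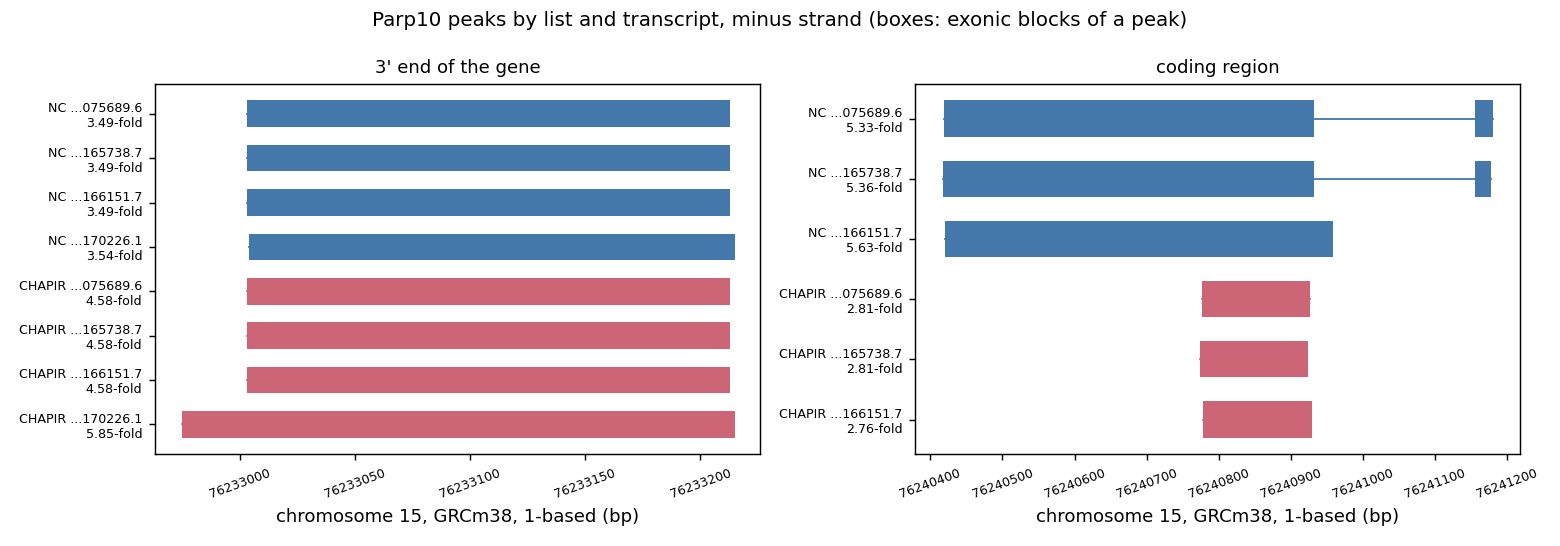
Parp10 peaks by transcript (vertical axis, with the authors' fold) against position on chromosome 15 (horizontal axis, GRCm38, bp), in the NC list (blue) and the CHAPIR list (red), near the 3' end and in the coding region. Boxes are exonic blocks and thin lines join blocks of 1 peak. The CHAPIR peaks of the coding region cover 155 bases inside the 566 exonic bases of the NC peaks.

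Among the other ADP-ribosylation genes, Parp14, Adprhl1 and Macrod1 were among those in both lists. Parp1 (4.14-fold), Parp2, Parp6, Tiparp, Adprh and Adprhl2 were among those NC only, and Parp4 (3.35-fold) and Parp8 (4.99-fold) were CHAPIR only. The 7 NC only members of 16 with a peak were matched or exceeded in 20.03% of random lists. With peaks at an FDR at or under 1e-05 in both lists, 2 of 7 members were NC only and none was CHAPIR only. With lists of equal length 3 of 12 were NC only, reached by 41.82% of random lists, and 3 were CHAPIR only.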

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

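Merged regions, 1 line per merged region, single-block peaks of at most 200 bases, genes in both lists, leaving out X and Y genes, and random lists matched on genomic span were chosen only after the data were seen. In every setting run, a larger share of CHAPIR than of NC peaks was overlapped, and the CDS held more of the NC and the 3' UTR more of the CHAPIR peaks, except that overlapped peaks had the opposite order for the CDS. The shares of overlapped peaks (NC, then CHAPIR) were 48.1% and 70.2% when 50% of the shorter peak had to overlap, 32.9% and 47.4% for 50% of both peaks, 56.8% and 71.1% at an FDR at or under 1e-05, 42.7% and 49.98% at a fold of at least 4, 63.0% and 66.6% for lists of equal length, 71.5% and 79.7% for peaks at that FDR against any peak, and 47.6% and 66.9% for merged regions. Whole spans and ignoring strand stayed within the intervals of the reported shares. The NC list kept 13013 peaks at that FDR and 9492 at that fold, and the CHAPIR list 10225 and 7887. Genes in both lists numbered 2247 at that FDR and 1745 at that fold. NC only genes numbered 1308 at that FDR, 1112 for lists of equal length and 698 at that FDR against any peak, and CHAPIR only genes numbered 488 in the last setting. With equal lengths CHAPIR only genes (1370) outnumbered NC only genes, because the NC peaks of larger p were left out. Restriction to protein-coding genes, or leaving out X and Y genes, kept all 3 counts within 1.5 times.

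CDS, 3' UTR and CDS with 3' UTR held 47.0%, 18.3% and 24.8% of NC and 34.1%, 34.9% and 22.9% of CHAPIR peaks at that FDR, and 46.1%, 20.2% and 21.6% of NC and 26.2%, 44.7% and 19.8% of CHAPIR peaks at that fold. For lists of equal length the NC shares were 47.9%, 20.4% and 22.5%. With 1 line per merged region they were 43.8%, 28.6% and 19.1% for NC, and 30.2% and 45.6% (CDS and 3' UTR) for CHAPIR. For short single-block peaks they were 40.0%, 43.5% and 9.71% for NC and 24.995%, 60.9% and 9.58% for CHAPIR. In genes of both lists they were 48.0% (CDS) and 19.9% (CDS with 3' UTR) for NC and 40.8%, 33.9% and 17.7% for CHAPIR. Among gene lists, CHAPIR only PARP genes made up 0% at the stricter FDR and NC only chromatin regulators 46.3%. For lists of equal length, NC only shares were 0% of oxidative phosphorylation genes, 29.8% of zinc finger genes and 5.88% of endothelial markers, and 16.7% of zinc finger genes were CHAPIR only. The cause of these shifts was not tested, beyond the fewer peaks that each stricter setting keeps. Gene list shares were recomputed at that FDR and for lists of equal length only, and the others stayed within their intervals, which are wide for small lists. Of the 21 gene lists, 1 had no member left in either setting and was not recomputed. Of the named genes with a peak, 178 kept their class at the stricter FDR and 57 did not, 144 and 91 at the fold of at least 4, and 216 and 19 for lists of equal length. Midpoint regions, distances from the stop codon, the DRACH, GGAC and RRACH motifs, the central part of peaks, genes by identifier or exon overlap, and random lists matched on exonic length were not run. No paired analysis was possible because each condition had 1 library of each kind and no test was made, and for that reason no replicate could be left out. Depth is unknown, so the absence of a peak is not evidence of absent methylation.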

Other observations

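The tests of the FDR of respiratory genes, of the 5' UTR share, of Xist and Tsix, and of further Y-linked genes were chosen only after the result was seen, as were the span-matched random lists and the setting with short peaks.

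Immediate early genes carried peaks in both lists for 11 of 18 members, led by the AP-1 genes Jun and Jund with Gadd45g and Ier5. Myc, Zfp36, Btg2, Nr4a1 and Junb were CHAPIR only and Fosl2 and Gadd45b were NC only. Clock genes had 7 of 12 in both lists, among them Dbp, Tef, Bhlhe40 and Bhlhe41. The clock repressor genes Per2 (4.51-fold) and Cry2 (2.54-fold) were NC only, and Nr1d1 (9.94-fold) and Ciart (17.7-fold) were among those CHAPIR only. The CHAPIR only counts were reached by 12.5% of random lists for immediate early genes and by 27.4% for clock genes. With peaks at an FDR at or under 1e-05, 7 of 17 immediate early genes were CHAPIR only (41.2%), a count reached by 2.35% of random lists. Only 5 genes were CHAPIR only among all peaks, so the rest of the 7 had an NC peak of larger FDR. With lists of equal length 7 of 17 were CHAPIR only, reached by 9.35%. The count of 5 was reached by 34.17% of random lists matched on genomic span.

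Vascular and stromal markers had NC only and CHAPIR only counts that random lists often reached. Of 21 endothelial markers with a peak, 15 were in both lists, including Cdh5, Kdr, Eng and Ptprb. The Notch ligand genes Dll4 (5.56-fold) and Jag1, the receptor genes Tek and Flt4, and Sox17 were NC only, and Tie1 was CHAPIR only. Of 29 fibroblast and matrix genes, 17 were shared, including Col3a1, Col4a1, Col6a1 and Pdgfra. Postn, Col5a1, Col6a3, Tgfb2, Tgfbr2 and Tgfbr3 were among the 7 NC only genes, and Dcn, Vim, Lum, Mmp2 and Vcan were CHAPIR only. Of 12 smooth muscle and pericyte markers, 7 were shared, 4 (Synm, Mylk, Notch3 and Cspg4) were NC only and Acta2 was CHAPIR only.

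Nuclear-encoded oxidative phosphorylation genes were CHAPIR only more often than other genes with a peak, and ribosomal protein genes and macrophage markers were too. Genomic span, introns included, is argued against, since 0% of random lists matched on it reached the 29 respiratory members. Exonic length and expression were not matched and stay open. In 25 of the 29 the best peak had an FDR at or under 1e-05, so most were not close to the threshold in the CHAPIR list. That FDR cannot show how close the NC library came to a peak, so peaks narrowly missed there stay open. A candidate explanation is that the CHAPIR libraries recovered more sequence from 3' ends, which was not tested on its own. The best peak touched the 3' UTR in 25 of the 29 (86.2%) and in 68.2% of all CHAPIR only genes. A peak on a short mRNA reaches the 3' UTR easily, and exonic length was not known, so the 86.2% does not decide this. A different share of cell types in the hearts, expression in the input, and the CHAPIR treatment all stay open and untested, because each condition had 1 library of each kind.

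The larger CDS share of NC peaks and larger 3' UTR share of CHAPIR peaks might come from the wider NC peaks. That is argued against as the whole cause, since among single-block peaks of at most 200 bases the 3' UTR share was still 17.4 percentage points higher in the CHAPIR list. Loss of 5' sequence in the CHAPIR libraries, as from degraded RNA, cannot be told apart from other causes. The ratio of 5' UTR shares over all coding peaks was 0.956, close to equal, but among short peaks the shares were 2.82% (2.41 to 3.31) in the CHAPIR list and 4.22% (3.70 to 4.81) in the NC list. The CHAPIR treatment and a difference between the libraries stay open, as untested.

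Xist had 10 lines and Tsix 2 lines in the NC list and none in the CHAPIR list, while Ddx3y (3.01-fold, FDR 0.000282) and Eif2s3y (2.77-fold, FDR 0.00123) had peaks in the CHAPIR list only. The Xist and Tsix peaks overlap on opposite strands and may share reads. A strong peak missed by chance cannot be told apart from other causes for them: 0.174% (1 of 575, Eif3b) of the other NC genes with an FDR as small lacked a CHAPIR peak, but Xist and Tsix were picked as NC only genes of smallest FDR, which kept that count low. For Ddx3y and Eif2s3y a weak peak missed at the threshold could account for the pattern, since 37.0% (373 of 1009) of other CHAPIR genes with an FDR as large lacked an NC peak. Hearts of animals of different sex could give this pattern and cannot be told apart from other causes. Of Kdm5d, Uty and Usp9y, 0 had a peak in either list. On the Y chromosome, the gene model Gm20775 had 1 NC line of 90 bases (11.8-fold, FDR 0.00891). Erdr1 had peaks in both lists (best FDR 0.00038 in NC and 0.0257 in CHAPIR). Their reads may come from similar copies elsewhere, so these weak peaks do not settle whether the NC tissue carried a Y chromosome. The NC peaks of Xist, the X-inactivation transcript, covered 2815 exonic bases with a best FDR of 5.01e-43. A difference in sex therefore stays open. Of the X-linked partners of Y genes, looked at after the data were seen, Kdm5c and Kdm6a were NC only, and Ddx3x, Eif2s3x, Uba1 and Usp9x were in both lists. Without X and Y genes the classes held 3485, 2020 and 993 genes, so few of the genes counted lie on these chromosomes. This does not test whether a difference in sex changed peaks on the other chromosomes.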
